A study of Homo sapiens with 12 samples.

How the data were processed

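Gene expression was measured in 12 samples of total RNA from 3 head and neck cancer cell lines, labelled Detroit, Fadu and OECM1. Fadu is a squamous carcinoma line of the hypopharynx and OECM1 a squamous carcinoma line of the oral cavity. Which of the Detroit lines was used is not given in the sources used here. For each line the labels name parent cells and an invasion subline, which was obtained by passage through Matrigel, a basement membrane extract, to collect strongly invasive cells. Each of the 6 groups held 2 samples. Per the labels, RNA was extracted with Trizol, labelled with biotin and hybridised to Affymetrix arrays, 1 array per sample.

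The deposited values were log2 expression values for 22283 probe sets per array, made by the authors with RMA (robust multi-array average, which subtracts background, brings the arrays to one distribution and summarises the probes of each probe set), and Partek version 7 was also used, per the submitters' processing notes. No value was missing, and no genome build or annotation was given in the sources used here. RMA compresses low values, so fold changes of weakly expressed genes are understated, and the table holds no detection calls. No read depth exists for arrays, and precision was limited by the number of arrays.

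Probe sets were named through the platform annotation. Of the probe sets that are not controls, 19065 had 1 gene symbol, 1043 had several and 2107 were not listed with a gene. The gene identifiers of 19053 were found in the reference gene table, and 0 symbols changed through it. The 68 control probe sets were used only for quality. Genes were named only from probe sets with 1 symbol, and a gene was represented by the probe set with the highest mean over the 12 arrays, which left 11963 genes. Genes were kept if at least 2 arrays lay above the 40th percentile of all values, a log2 value of 4.52, and 8992 genes were tested. There were 0 unused columns of values. Affymetrix probe sets of near-identical genes, such as the AKR1C, HLA and S100A families, can share signal.

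A linear model with a mean for each of the 6 groups was fitted to the 12 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend. The 6 groups shared 1 estimate of the spread because each held 2 arrays. Each invasion subline was set against the parent of its line. The 3 effects were also tested for a difference between lines with an F test, the 3 parents were compared with an F test, and an average effect was fitted to the 6 group means with the line as a block, so that 3 line pairs were the replicates. P-values were adjusted by the Benjamini-Hochberg method over the 8992 genes, with a threshold of 0.05. The labels do not say whether duplicates came from separate cultures. P-values therefore measured only the spread between these samples, which may be technical.

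Before the data were examined, 30 gene lists were fixed, which covered invasion, epithelial and squamous state, signalling, metabolism, cell cycle and markers of fibroblasts, endothelial cells and leukocytes. List shifts were tested with camera at a preset correlation between genes of 0.01, adjusted over 120 tests of 30 lists and 4 contrasts. In the list tests the average was the mean of the line contrasts fitted to the single arrays. Duplicates, and not line pairs, were therefore its replicates. Camera with an estimated correlation and fry were run beside it. Small nucleolar RNAs had 1 gene on the array and were not tested. Counts of members called with adjustment over the list alone stand beside those over all genes.

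The genes named in the text followed a rule written before the data were examined. It took the genes called the same way in all 3 lines, up to 6 higher and 6 lower called genes per line whose 2 invasion arrays both lay beyond the 2 parent arrays, ranked by fold change, genes called in opposite directions, up to 4 called members of each list, and genes called on average. After the counts of called genes had been seen, lists with fewer than 4 called members were filled to 4 with the members of smallest p. Genes added in that way are described by their values, and an adjusted p is given for only a part of them. By the rule, none of the added genes was called over all genes.

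The fitting steps were tested on simulated arrays, in 10 runs with 200 changed genes each. Each subline took the real mean of its parent, and 1 real spread per gene served all 6 groups. Near-equal recovery in the 3 lines follows from that setting. The same change was planted in every line with no variation between lines, so the share for the average holds only for that case. Among genes changed 4-fold, 65.4% were recovered for Detroit, 66.1% for Fadu, 65.6% for OECM1 and 84.2% for the average over 3 line pairs. Among genes changed 2-fold, these shares were 12.0%, 11.5%, 10.8% and 21.0%. In 10 further runs, a list of 25 genes shifted by 0.5 on the log2 scale in the Fadu comparison was found 10 times, with 0 calls among 290 unshifted lists. The simulated genes varied independently, which real genes of a pathway do not.

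Alternatives covered the filter on dim genes, the choice of probe sets, normalization, the variance model, array weights, thresholds, the replicate number as a block, the arrays in the fit, the list test and leaving out each array in turn. Alternatives added after the data were seen were a block that pairs invasion replicate 1 with parent replicate 2, the ratio of the 3 prime to the 5 prime ACTB control probe set as a covariate, fits without the 4 arrays labelled Detroit, and the NRF2 list without its AKR1C genes. That ratio rises where RNA is degraded or labelling is short. Plots were drawn with matplotlib 3.10.9.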

Results

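Expression was measured on 12 arrays from 3 head and neck cancer lines, each as parent cells and as a subline selected for invasion through Matrigel, with 2 arrays in each of the 6 groups. The comparisons address which transcripts accompany selection for invasion, within each line and across lines. Values are log2 RMA values. Array medians lay between 4.92 and 5.06. Fold changes are invasion subline over parent, with the standard error (SE) of the log2 fold change from the limma fit, n = 2 arrays per group, and p-values adjusted by the Benjamini-Hochberg method.

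The 12 arrays did not all resemble the other arrays of their labelled line. Across 8992 genes, which are not independent replicates, the mean of the arrays labelled Detroit invasion subline correlated with the Fadu parent mean at r = 0.961 and with the Detroit parent mean at r = 0.881. The root mean square log2 difference was 0.45 to the Fadu parent and 0.77 to the Detroit parent. For the other lines, subline and parent correlated at r = 0.978 in Fadu and r = 0.972 in OECM1. The Detroit and Fadu parents themselves correlated at r = 0.906. Between the arrays labelled Detroit invasion subline and the Fadu parent, limma called 0 genes, with 351 at an unadjusted p under 0.05, while 232 genes separated the Detroit and Fadu parents and 295 separated the arrays labelled Detroit invasion subline from the Detroit parent. The labels name Detroit for these arrays. Whether that name holds was not settled here, and every Detroit value compares the groups as labelled.

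**Figure D1:**
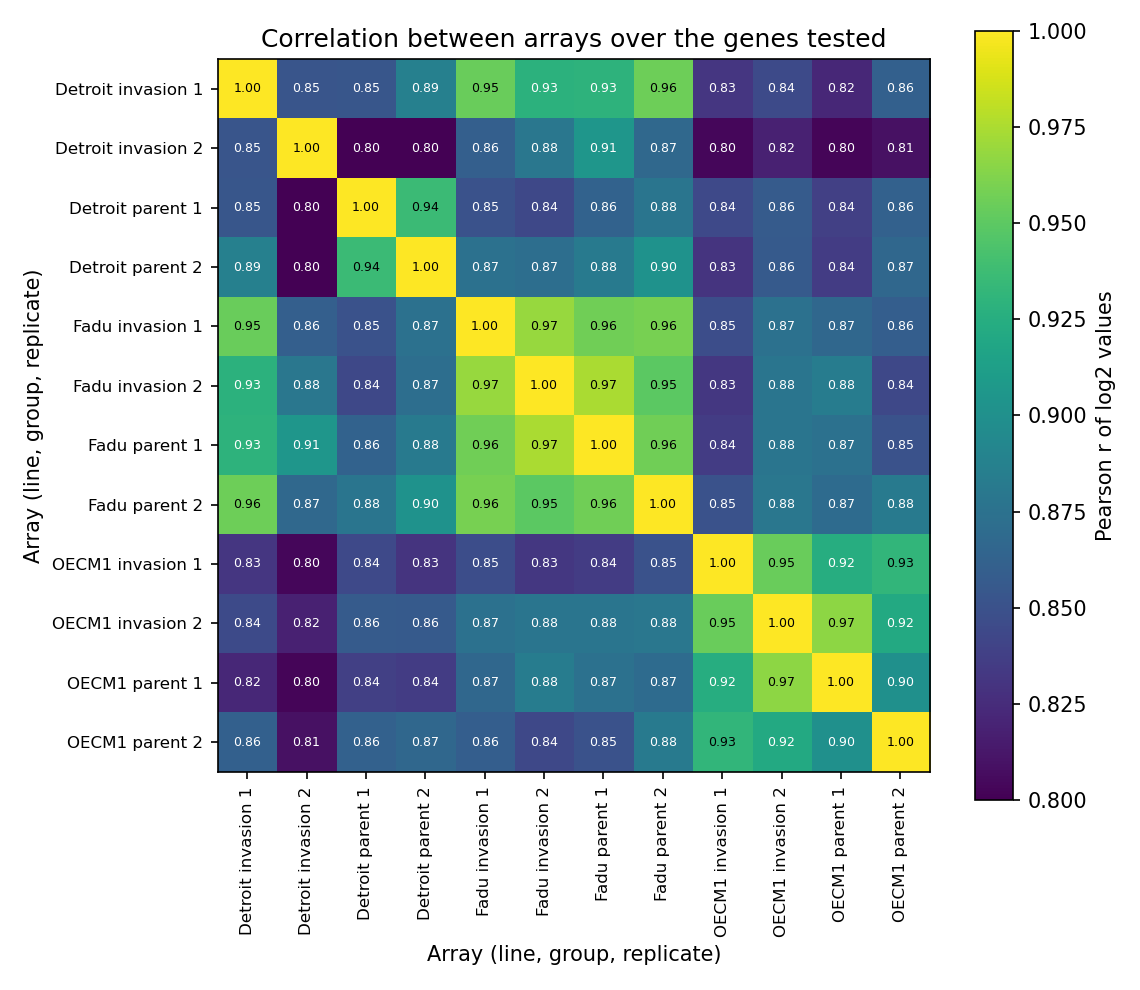
Pearson correlation of log2 values between every pair of the 12 arrays over the genes tested, with arrays on both axes ordered by line, group and replicate and colour showing r. The array labelled Detroit invasion 1 correlates more closely with each of the 4 Fadu arrays than with either Detroit parent array, and the 2 arrays labelled Detroit invasion correlate at r = 0.853.

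Duplicates of most groups also differed in a control measure that can reflect RNA quality or labelling. The log2 difference between the 3 prime and 5 prime ACTB control probe sets, which rises with RNA degradation or short labelling, was -0.28 and 0.80 in the 2 arrays labelled Detroit invasion subline and -0.03 and -0.10 in the Detroit parent. It was -0.05 and 0.40 in the Fadu invasion subline, 0.55 and -0.23 in the Fadu parent, 0.06 and 0.63 in the OECM1 invasion subline, and 0.87 and 0.04 in the OECM1 parent, with replicate 1 given first. Duplicates of the arrays labelled Detroit invasion subline differed by a root mean square of 0.89, the OECM1 parent duplicates by 0.75 and the Fadu invasion subline duplicates by 0.42. No pair of duplicates held one array deposited again, since at most 2 of the 8992 values were identical within a pair.

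The Detroit comparison asked which genes differed between the arrays labelled Detroit invasion subline and the Detroit parent. KRT14 and the protease genes KLK5 and PRSS21 were far higher in these arrays, and S100A8, S100A9, MMP7, PLAT and CXCL1 were far lower. KRT14, a keratin of basal keratinocytes, was 88.4-fold higher (log2 fold change 6.47, SE 0.619, adjusted p = 0.000203, limma), and KLK5, a kallikrein protease of the epidermis, was 27.8-fold higher. S100A8 and S100A9, the subunits of calprotectin, were 192-fold lower (log2 fold change -7.59, SE 0.308, adjusted p = 6.10e-07) and 33.4-fold lower. MMP7, which encodes the metalloproteinase matrilysin, was 38.0-fold lower, and PLAT, the tissue plasminogen activator, was 32.4-fold lower. In each gene given here with a fold both subline arrays lay beyond both parent arrays. The limit below which genes were left out as dim was a log2 value of 4.52, and both Detroit parent arrays lay below it for KRT14 and KLK5, as did both subline arrays for S100A8, MMP7 and PLAT, so the size of these folds rests on low signals that RMA compresses.

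Other genes with large increases were PRSS21, a serine protease gene, at 44.6-fold, SHANK2, a scaffold protein gene, at 26.2-fold, EEF1A2, an elongation factor gene, at 22.4-fold, and ARHGAP29 at 21.1-fold. Large decreases were seen for SLC1A3, a glutamate transporter gene, at 42.3-fold, and CXCL1, a neutrophil-attracting chemokine, at 33.1-fold. Both Detroit parent arrays lay below the dim limit for PRSS21 and SHANK2. A second probe set of S100A8 gave a log2 fold change of only -0.83. The Fadu parent levels of these genes lay on the same side of the Detroit parent as the subline. KRT14 averaged 10.52 ± 1.41 (SD, n = 2) in the arrays labelled Detroit invasion subline, 4.05 ± 0.0813 in the Detroit parent and 8.87 ± 0.298 in the Fadu parent. S100A8 averaged 3.43 ± 0.393, 11.01 ± 0.553 and 4.54 ± 0.242 in the same groups. Across all calls, 295 genes passed, 136 higher and 159 lower, and 292 of the 295 lay nearer to the Fadu parent mean than to the Detroit parent mean, against 242 nearer to the OECM1 parent mean. The count of calls was 47 with only the 4 arrays labelled Detroit, 118 with the replicate number as a block within each line and 170 with array weights. The count also depended on single arrays. It was 918 without Detroit invasion subline replicate 1, 128 without Detroit parent replicate 1 and 191 without Detroit parent replicate 2. The CXCL1 call ended without Detroit parent replicate 1 (log2 fold change -4.55, adjusted p = 0.0712).

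**Figure D2:**
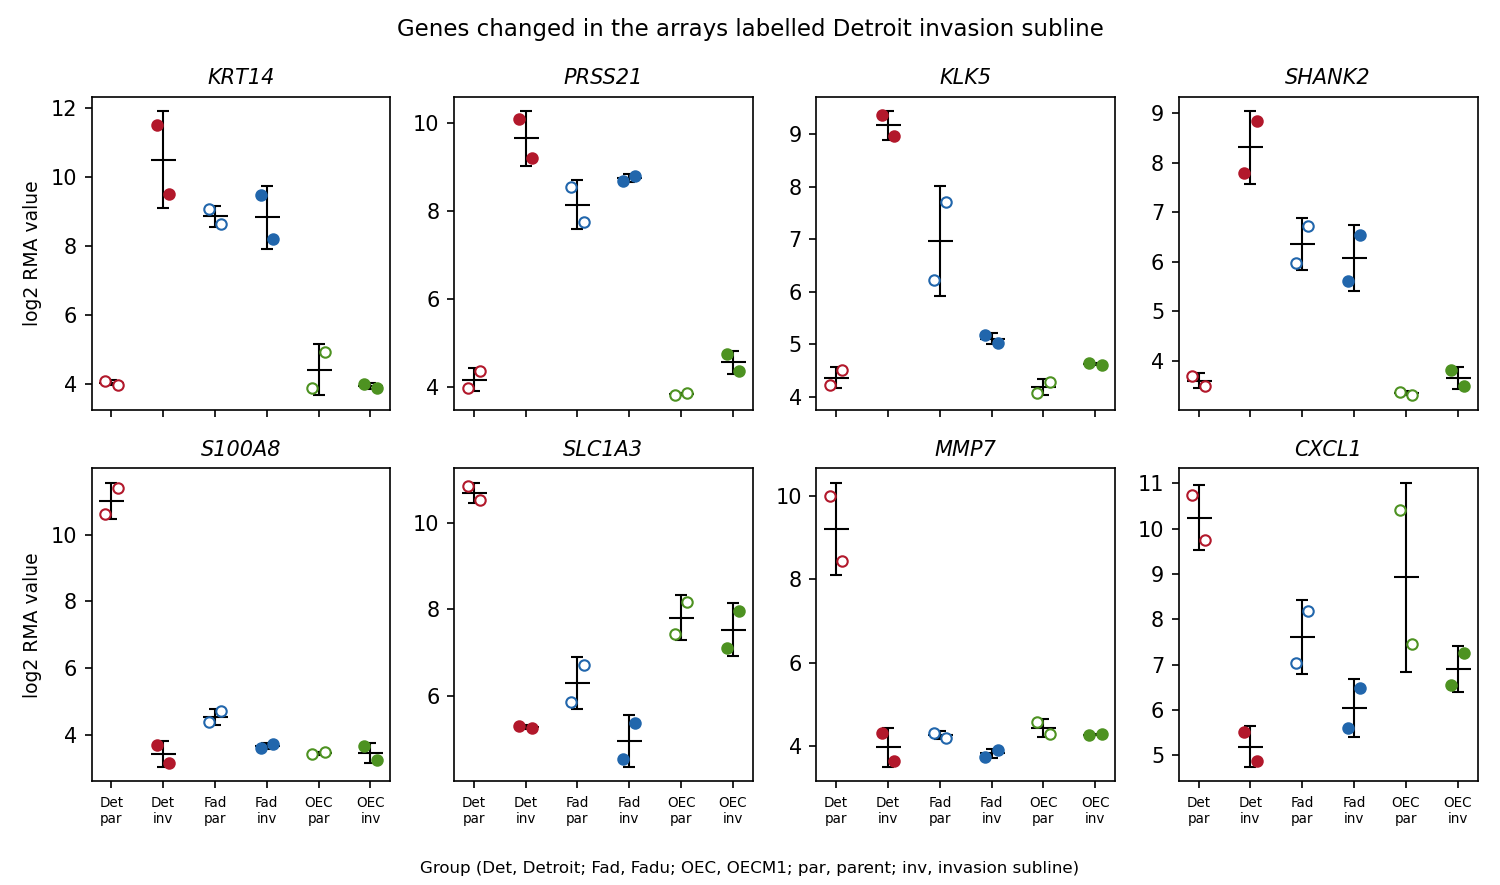
Log2 RMA value (vertical axis) of 8 genes in each of the 6 groups (horizontal axis), with points for arrays, open for parents and filled for sublines, and bars for the mean and SD of 2 arrays. KRT14 averages 4.05 in the Detroit parent, 10.52 in the arrays labelled Detroit invasion and 8.87 in the Fadu parent.

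Genes of the extracellular matrix and its turnover were lower as groups in the arrays labelled Detroit invasion subline. Of 27 measured matrix proteases and inhibitors, 9 fell, 0 rose and 18 did not pass (11 lower when adjusted over the list alone), with a mean log2 fold change of -1.43. Besides MMP7 and PLAT, the stromelysin gene MMP10 was 24.0-fold lower and the collagenase gene MMP1 was 22.2-fold lower. Of 20 collagens and other matrix proteins, 4 fell and 16 did not pass (6 lower over the list alone), among them COL5A2 at a log2 fold change of -4.17, the fibronectin gene FN1 at 12.4-fold, THBS1 at 10.4-fold and COL4A1 at 5.07-fold. Both subline arrays lay below the dim limit for MMP10 and COL5A2. Camera called both lists lower (adjusted p = 1.05e-07 and 0.000364). Neither call held with an estimated correlation (adjusted p = 0.304 for the proteases and adjusted p = 0.564 for the collagens). The Fadu parent lay below the Detroit parent by a mean of 1.11 for the proteases and 1.05 for the collagens on the log2 scale. The MMP1, THBS1 and COL4A1 calls ended without Detroit invasion subline replicate 2 (adjusted p = 0.152, 0.106 and 0.130) and without Detroit parent replicate 1 (adjusted p = 0.142, 0.214 and 0.157), the FN1 call without Detroit parent replicate 1 (adjusted p = 0.0865), and the MMP1 call also without Detroit parent replicate 2 (adjusted p = 0.198).

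Inflammatory, TGF-beta response and interferon genes were also shifted in the arrays labelled Detroit invasion subline. Of 27 NF-kB and inflammatory cytokine genes, 5 fell and 22 did not pass (7 lower and 1 higher over the list alone), including the complement gene C3 at 26.2-fold and the chemokine genes CXCL6 at 13.7-fold and CXCL3 at 10.8-fold. Both subline arrays lay below the dim limit for CXCL6 and CXCL3. Of 21 TGF-beta response genes, 4 fell and 17 did not pass (7 lower over the list alone), with TGFBI, a matrix protein gene, 24.6-fold lower, ID3, an inhibitor of bHLH factors, 10.3-fold lower and BAMBI, a pseudoreceptor gene, 2.87-fold lower. Of 31 interferon stimulated genes, 3 rose and 28 did not pass (3 over the list alone), namely IFI27 at 13.7-fold, ISG15 at 6.43-fold and ISG20 at 3.67-fold, while IRF9 had a log2 fold change of 1.42 (adjusted p = 0.133). Camera called the NF-kB list lower (adjusted p = 0.0109), the TGF-beta list lower (adjusted p = 0.00686) and the interferon list higher (adjusted p = 0.0366). With an estimated correlation the adjusted p = 0.564 for the NF-kB list, 0.564 for the TGF-beta list and 0.858 for the interferon list. The Fadu parent differed from the Detroit parent by a mean of -0.27, -0.92 and 1.44 for these 3 lists. Without Detroit invasion subline replicate 1 the list calls ended (adjusted p = 0.0871, 0.0905 and 0.829), and without Detroit parent replicate 1 those of NF-kB and TGF-beta ended (adjusted p = 0.195 and 0.148). The interferon call also ended without Detroit parent replicate 2 (adjusted p = 0.0736) and without OECM1 parent replicate 1 or 2 (adjusted p = 0.0760 and 0.0664). With the ACTB ratio as a covariate, a setting chosen after the data were seen, its mean was 0.44 and the call ended (adjusted p = 0.110). Leaving out Detroit parent replicate 1 also ended the calls of C3, BAMBI, IFI27, ISG15 and ISG20 (adjusted p = 0.112, 0.146, 0.0810, 0.178 and 0.146). C3 and ISG20 missed the threshold without Detroit invasion subline replicate 2 (adjusted p = 0.0568 and 0.0630), ISG15 without replicate 1 (adjusted p = 0.0608), and C3, IFI27, ISG15 and ISG20 without Detroit parent replicate 2 (adjusted p = 0.0516, 0.102, 0.0759 and 0.0943).

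Antioxidant, stem cell associated and antigen presentation genes were lower by smaller means. Of 25 NRF2 and xenobiotic metabolism genes, 4 fell and 21 did not pass (8 lower and 2 higher over the list alone), with AKR1C3 at 16.3-fold, AKR1B10 at 5.24-fold, the glutathione peroxidase gene GPX2 at 4.13-fold and the aldehyde dehydrogenase gene ALDH3A1 at 3.92-fold. Both subline arrays lay below the dim limit for AKR1C3 and AKR1B10. Of 13 stem and drug tolerance associated genes, 3 fell, 1 rose and 9 did not pass (5 lower and 1 higher over the list alone), with CD24, a surface glycoprotein gene, 9.51-fold lower, NGFR 2.42-fold lower and the transcription factor gene SOX9 2.94-fold higher. Of 15 MHC and antigen presentation genes, the immunoproteasome gene PSMB9 fell 3.52-fold and 14 did not pass (3 lower over the list alone), among them HLA-DRA (log2 fold change -1.57, adjusted p = 0.0572), PSMB8 (-1.34, adjusted p = 0.0693) and TAP2 (-1.19, adjusted p = 0.166), whose second probe set gave 0.04. Camera called the 3 lists lower (adjusted p = 0.0119, 0.0208 and 0.00686). The same lists had adjusted p = 0.564, 0.564 and 0.697 with an estimated correlation. The Fadu parent differed from the Detroit parent by a mean of -0.66, -0.56 and -0.05 for the 3 lists. The NRF2 mean of -0.55 turned to 0.07 without Detroit invasion subline replicate 1 (adjusted p = 0.829), where the stem list call also ended (adjusted p = 0.117). Without its AKR1C genes, a setting chosen after the data were seen, the NRF2 mean was -0.15 and the call ended (adjusted p = 0.191). The stem and antigen presentation calls ended without Detroit parent replicate 1 (adjusted p = 0.148 and 0.413), and the latter without Detroit invasion subline replicate 2 (adjusted p = 0.132). Without Detroit invasion subline replicate 2 the calls of ALDH3A1, NGFR, PSMB9 and SOX9 ended (adjusted p = 0.0582, 0.146, 0.106 and 0.112), as they did without Detroit parent replicate 1 (adjusted p = 0.0904, 0.214, 0.0979 and 0.171). The last 3 also ended without Detroit parent replicate 2 (adjusted p = 0.0944, 0.0943 and 0.0969).

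Cell cycle and unfolded protein response genes lay apart in the 2 arrays labelled Detroit invasion subline. Against the Detroit parent mean, the 31 G2 and mitosis genes averaged 0.09 in replicate 1 and -2.94 in replicate 2, and the 29 S phase genes averaged 0.11 and -1.93. The 21 unfolded protein and ATF4 response genes averaged -0.09 in replicate 1 and 2.36 in replicate 2, the array with the higher ACTB ratio of 0.80. In the OECM1 parent the order was the reverse, since the array with a ratio of 0.87 had the lower mean of this list. The OECM1 mean log2 fold change of 0.53 was 0.07 without that array. AURKA, a mitotic kinase gene, averaged 6.97 ± 2.49 (SD, n = 2) in the subline and 9.19 ± 0.462 in the parent, a log2 fold change of -2.22 (adjusted p = 0.214). The replication gene CDC45 had a log2 fold change of -2.75 (adjusted p = 0.105), the cyclin gene CCNE2 -1.73 (adjusted p = 0.0528), RFC4 -1.81 (adjusted p = 0.0836) and CHAF1B -1.13 (adjusted p = 0.137). Among mitotic genes CENPE had -0.97 (adjusted p = 0.124), CENPF -1.82 (adjusted p = 0.153) and CCNB2 -1.85 (adjusted p = 0.199), and a second CENPF probe set gave -0.20. CRELD2, a chaperone-associated gene of the endoplasmic reticulum, rose 6.95-fold (adjusted p = 0.00525), and the other 20 members did not pass (1 higher over the list alone), with PHGDH at 1.83, MANF at 1.44 and PDIA4 at 1.47 (adjusted p = 0.115, 0.140 and 0.202). The 18 cholesterol synthesis genes averaged -0.33 and -0.59 in the 2 arrays. Of these 0 passed, and DHCR7 had a log2 fold change of -1.74, NSDHL -1.21, ACAT2 -1.04 and HMGCS1 -0.83 (adjusted p = 0.0782, 0.256, 0.265 and 0.277), with -0.38 in a second HMGCS1 probe set.

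Camera called the G2 and mitosis list lower in that comparison (mean -1.42, adjusted p = 4.96e-07), as well as S phase genes (-0.91, adjusted p = 0.000598) and cholesterol genes (-0.46, adjusted p = 0.0213), and called the unfolded protein list higher (1.14, adjusted p = 0.000343). With an estimated correlation the adjusted p = 0.737, 0.756, 0.564 and 0.756. With the ACTB ratio as a covariate, a setting chosen after the data were seen, the camera calls of these lists held. Without Detroit invasion subline replicate 2 the G2 and mitosis, S phase and unfolded protein means turned to 0.09, 0.11 and -0.09 (adjusted p = 0.839, 0.807 and 0.804), and the cholesterol call ended (adjusted p = 0.107). The Fadu parent lay 0.08 and 0.02 above the Detroit parent for G2 and mitosis and S phase genes, 0.39 above it for cholesterol genes and 0.10 above it for unfolded protein genes.

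In the Fadu comparison, an antioxidant enzyme gene and an interferon-induced gene were lower in the invasion subline than in its parent. GPX2, a glutathione peroxidase of epithelia, was 8.07-fold lower (log2 fold change -3.01, SE 0.317, adjusted p = 0.00992, limma), at 5.44 ± 0.209 against 8.45 ± 0.579 (SD, n = 2 arrays each). BST2, which encodes the antiviral membrane protein tetherin, was 7.36-fold lower (log2 fold change -2.88, SE 0.319, adjusted p = 0.00992), at 5.05 ± 0.416 against 7.93 ± 0.540. These 2 genes were the only calls, both lower, and 182 genes had an unadjusted p under 0.05 where 449.6 were expected by chance. The spread was pooled over the 6 groups, with a median SE of 0.351 in each line. Duplicates differed by a root mean square of 0.42 and 0.48 in Fadu but 0.89 in the arrays labelled Detroit invasion subline. Few calls therefore need not mean little change. With only the 4 Fadu arrays neither gene was called, and SCNN1A was (log2 fold change -3.20, adjusted p = 0.0236, limma). Fadu invasion subline replicate 1 had an 18S control value of 12.68, against 5.74 in replicate 2. The GPX2 call ended without Fadu invasion subline replicate 1 or 2 or Fadu parent replicate 2 (adjusted p = 0.0960, 0.139 and 0.0844), and the BST2 call without Fadu invasion subline replicate 1 or Fadu parent replicate 1 (adjusted p = 0.178 and 0.0669). The count was 0 without Fadu invasion subline replicate 1, 1 without Fadu parent replicate 2 and 0 with the replicate number as a block within each line.

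Groups of detoxification, squamous differentiation and cholesterol synthesis genes lay lower in the Fadu invasion subline. The 25 NRF2 and xenobiotic metabolism genes averaged -0.60, with 19 of them lower, 1 called (2 over the list alone) and 24 not passing. Besides GPX2, ALDH3A1 had a log2 fold change of -1.88 (adjusted p = 0.420), and the aldo-keto reductase genes AKR1C1 and AKR1C2 had -1.96 and -1.98 (adjusted p = 1.00 for both), with -0.93 in a second AKR1C1 probe set. The 28 squamous differentiation genes averaged -0.63, with 20 lower and 0 called (3 lower over the list alone). The kallikrein genes KLK10, KLK5 and KLK6 had log2 fold changes of -2.25, -1.86 and -2.44 and S100A9 had -1.09 (adjusted p = 0.823, 0.823, 1.00 and 0.944), and a second KLK10 probe set gave -0.59. The 18 cholesterol synthesis genes averaged -0.57, with 16 lower and 0 called (2 lower over the list alone), among them HMGCS1 at -1.52, LSS at -1.16, INSIG1 at -2.05 and DHCR7 at -0.98 (adjusted p = 0.944, 1.00, 1.00 and 1.00), and a second LSS probe set gave -0.27. Camera called the 3 lists lower (adjusted p = 6.40e-07, 3.00e-06 and 5.22e-06). Each had an adjusted p = 0.304 with an estimated correlation.

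Inflammatory, junction and antigen presentation genes also lay lower in the Fadu invasion subline, and cell cycle, YAP target and matrix genes lay higher. The 27 NF-kB and inflammatory cytokine genes averaged -0.48 with 20 lower and 0 called, among them TNFSF10 at -2.19, TNFAIP2 at -1.70 and CXCL2 at -1.17, while IL6 had 1.36 (adjusted p = 1.00 for the 4) and a second TNFAIP2 probe set gave -0.38. The 26 epithelial junction genes averaged -0.31 with 18 lower and 0 called, among them the claudin gene CLDN4 at -0.89, ELF3 at -1.37, RAB25 at -0.85 and the desmocollin gene DSC3 at -0.75, with -0.34 in a second probe set. The 15 antigen presentation genes averaged -0.25 with 12 lower and 0 called, including PSMB8 at -0.61, HLA-DMB at -0.39, TAPBP at -0.66 and HLA-E at -0.46, and a second TAPBP probe set gave -0.16. Camera called these lists lower (adjusted p = 0.00108, 0.00243 and 0.0446). With an estimated correlation the adjusted p = 0.564, 0.304 and 0.756. Over the lists alone 0 members of these 3 passed.

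Of 31 G2 and mitosis genes, 30 lay higher in the Fadu invasion subline with a mean of 0.53, among them NEK2 at 1.18, TTK at 1.17, KIF23 at 1.03 and CKAP2 at 0.88, and 0 were called. The 29 S phase genes averaged 0.24 with 26 higher, including RRM1 at 0.88, GINS1 at 0.70, RFC4 at 0.55 and CCNE2 at 0.41, and CCNE2 turned to -0.01 without Fadu invasion subline replicate 2. A second RRM1 probe set gave 0.38. The 19 YAP and TEAD target genes averaged 0.35 with 14 higher, including CCN2 at 1.66, NT5E at 1.27, AXL at 1.22 and F3 at 0.73. The 20 collagens and other matrix proteins averaged 0.33 with 11 higher, including COL4A1 at 1.93, COL4A2 at 1.62, TNC at 0.92 and FBN2 at 0.66, and second probe sets gave -0.03 for TNC and -0.05 for FBN2. Over the lists alone 0 members of these 4 passed. Camera called them higher (adjusted p = 7.91e-05, 0.0446, 0.0109 and 0.0187). The same lists had adjusted p = 0.756, 0.895, 0.564 and 0.746 with an estimated correlation. The YAP and collagen calls ended without Fadu invasion subline replicate 1 (adjusted p = 0.106 and 0.241), the S phase call without replicate 2 (adjusted p = 0.332), and the collagen and S phase calls without Fadu parent replicate 1 (adjusted p = 0.226 and 0.371). Without OECM1 parent replicate 1 the collagen and S phase calls ended (adjusted p = 0.0546 and 0.0899), and so did the S phase call without OECM1 parent replicate 2 (adjusted p = 0.0804). The antigen presentation call ended without Fadu invasion subline replicate 1, Fadu parent replicate 1, OECM1 invasion subline replicate 1, OECM1 parent replicate 1 and OECM1 parent replicate 2 (adjusted p = 0.225, 0.706, 0.0511, 0.0760 and 0.0664). With no filter on dim genes the collagen mean was 0.20 and the antigen presentation mean -0.19, and both calls ended (adjusted p = 0.129 and 0.303). Quantile normalization run again ended the S phase call (mean 0.19, adjusted p = 0.0961). The ACTB covariate ended the S phase and antigen presentation calls (adjusted p = 0.0686 and 0.0799).

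**Figure D3:**
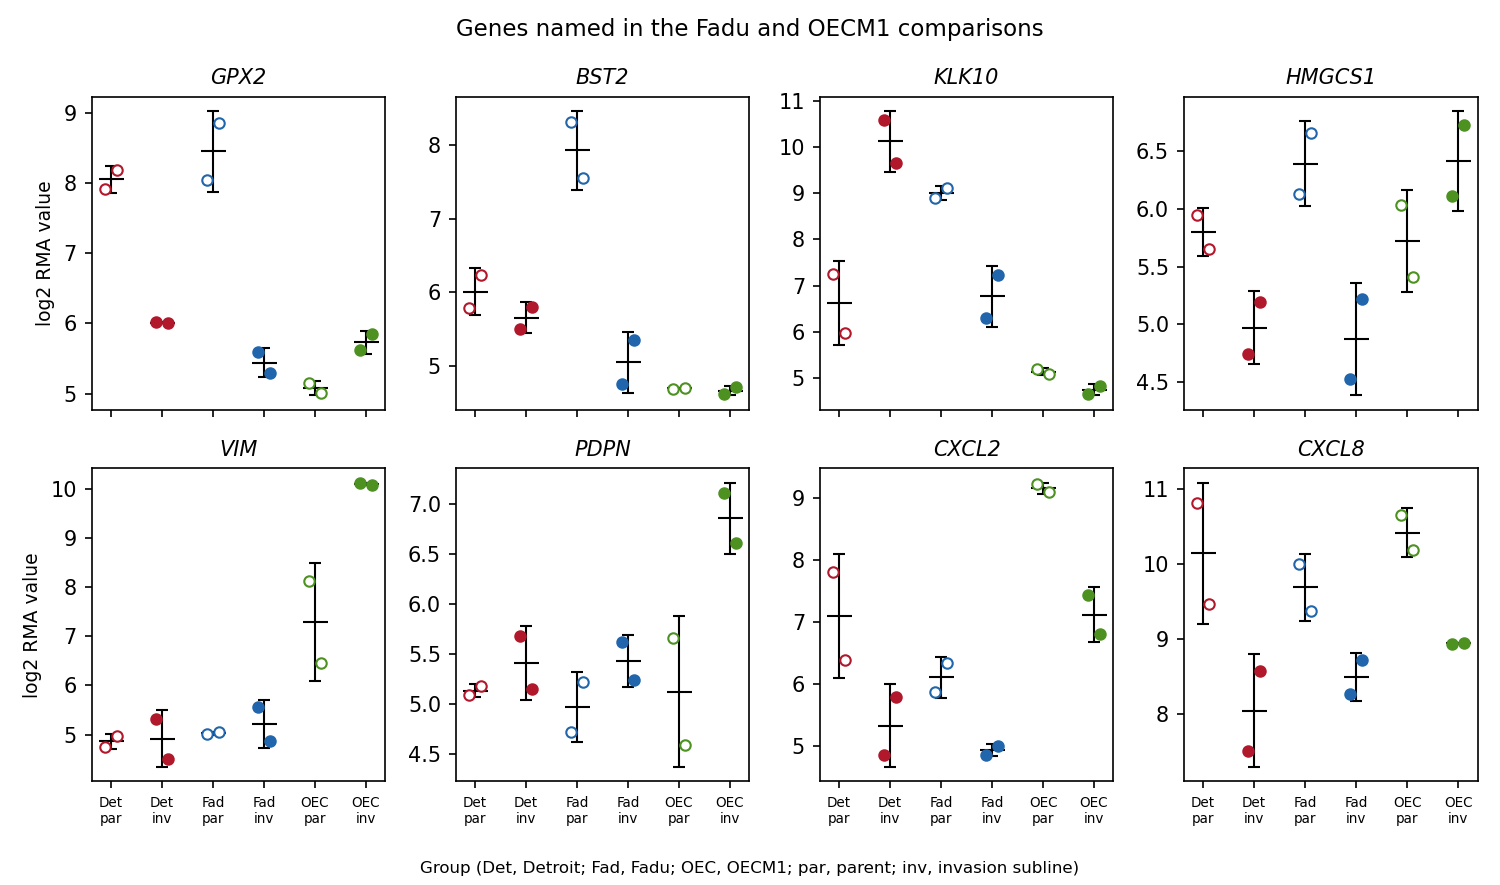
Log2 RMA value (vertical axis) of 8 genes in each of the 6 groups (horizontal axis), with points for arrays, open for parents and filled for sublines, and bars for the mean and SD of 2 arrays. GPX2 averages 8.45 in the Fadu parent and 5.44 in its subline, and the 2 OECM1 parent arrays differ widely in VIM, around a mean of 7.29.

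In the OECM1 comparison no single gene passed, and VIM and PDPN of the partial EMT list passed only with adjustment over the list alone. VIM, which encodes the intermediate filament vimentin, was at 10.10 ± 0.0299 in the invasion subline and 7.29 ± 1.19 (SD, n = 2 arrays each) in the parent, a log2 fold change of 2.81 (SE 0.490, adjusted p = 0.247, limma). PDPN, which encodes the membrane glycoprotein podoplanin, had a log2 fold change of 1.74 (SE 0.372, adjusted p = 0.391), and a second PDPN probe set gave 0.59. The spread was pooled over the 6 groups here too, so a lack of calls need not mean little change. The count of calls was 0, with 300 genes at an unadjusted p under 0.05 where 449.6 were expected by chance. Without OECM1 parent replicate 1 it was 6, with VIM among them (log2 fold change 3.65, adjusted p = 0.0279), and without OECM1 invasion subline replicate 1 it was 2.

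Genes of the partial EMT programme, matrix proteolysis, the unfolded protein response and TGF-beta signalling lay higher as lists in the OECM1 invasion subline. The 11 partial EMT genes averaged 0.67, with 8 higher, 0 called and 2 passing over the list alone (VIM and PDPN), while ITGA5 had 0.74 and the gelatinase gene MMP2 had -1.01. The 27 matrix proteases and inhibitors averaged 0.34 with 20 higher, among them the cathepsin genes CTSL at 1.25 and CTSD at 0.74 and the inhibitor gene TIMP3 at 0.63. The 21 unfolded protein and ATF4 response genes averaged 0.53 with 20 higher, including SDF2L1 at 1.09, PHGDH at 0.79, PDIA4 at 0.70 and MANF at 0.67, and PDIA4 turned to -0.12 without OECM1 invasion subline replicate 1. The 21 TGF-beta response genes averaged 0.41 with 16 higher, including IGFBP3 at 2.21, TGFB1 at 1.32 and BHLHE40 at 1.25, while ID3 had -1.20 and a second TGFB1 probe set gave -0.14. Camera called these lists higher (adjusted p = 0.00264, 0.00544, 0.00633 and 0.0107). With an estimated correlation the adjusted p = 0.564, 0.564, 0.756 and 0.564. The OECM1 parent duplicates had ACTB ratios of 0.87 and 0.04. Without OECM1 parent replicate 2 the partial EMT mean was 0.29 and the protease mean 0.06 (adjusted p = 0.299 and 0.451), and the TGF-beta call ended (adjusted p = 0.119). Without OECM1 parent replicate 1 the unfolded protein mean was 0.07 and the TGF-beta mean 0.41 (adjusted p = 0.820 and 0.101), and without OECM1 invasion subline replicate 1 they were 0.18 and 0.23 (adjusted p = 0.559 and 0.213).

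A further 3 lists lay higher in the OECM1 invasion subline and 2 lay lower. The 25 NRF2 and xenobiotic metabolism genes averaged 0.32 with 20 higher, including AKR1C1 at 1.46, TRIM16 at 0.86, GPX2 at 0.66 and AKR1C3 at 0.63. The 15 antigen presentation genes averaged 0.33 with 12 higher, including HLA-B at 1.17, HLA-C at 1.16, PSMB9 at 0.60 and B2M at 0.57. The 13 stem and drug tolerance associated genes averaged 0.41 with 10 higher, including KLF4 at 1.08, ALDH1A3 at 0.92 and SOX9 at 0.90, while NES had -0.31 and a second KLF4 probe set gave 0.25. The 29 S phase genes averaged -0.35 with 26 lower, including MCM3 at -0.88, MCM6 at -0.83, CCNE2 at -0.80 and POLA1 at -0.57, and MCM6 turned to 0.04 without OECM1 invasion subline replicate 1. The 27 NF-kB and inflammatory cytokine genes averaged -0.23 with 18 lower, including the chemokine genes CXCL2 at -2.04, CXCL1 at -2.03 and CXCL8 at -1.48, while PTGS2, the inducible cyclooxygenase, had 2.23. Over all genes 0 members of the 9 lists passed, and over the list alone 1 NF-kB gene was lower. Camera gave adjusted p = 0.0161, 0.0389, 0.0446, 0.0104 and 0.0446 for these 5 lists. The same lists had adjusted p = 0.564, 0.756, 0.564, 0.858 and 0.588 with an estimated correlation.

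Each of these 5 calls ended without single OECM1 arrays. Without OECM1 invasion subline replicate 1 the S phase mean turned to 0.09, with antigen presentation at 0.28 and NF-kB at -0.20 (adjusted p = 0.806, 0.115 and 0.120). Without OECM1 invasion subline replicate 2 the NRF2, antigen presentation, stem and NF-kB lists missed the threshold (adjusted p = 0.493, 0.0931, 0.257 and 0.0933). Without OECM1 parent replicate 1 the NRF2, stem, S phase and NF-kB lists did (adjusted p = 0.173, 0.612, 0.764 and 0.315), with S phase genes at -0.07 and NF-kB genes at -0.11. Without OECM1 parent replicate 2 the NRF2, antigen presentation and NF-kB lists did (adjusted p = 0.119, 0.633 and 0.0856), with antigen presentation genes at 0.13. The NRF2 call also ended without its AKR1C genes (mean 0.22, adjusted p = 0.0889). With no filter on dim genes the NF-kB and stem means were -0.20 and 0.25, and both calls ended (adjusted p = 0.0508 and 0.241). The mean of the probe sets of a gene ended the antigen presentation call (0.24, adjusted p = 0.165). The ACTB covariate ended the NF-kB, stem and antigen presentation calls (adjusted p = 0.0714, 0.0617 and 0.0714). The NF-kB call also ended without Detroit invasion subline replicate 1 or 2 or Fadu invasion subline replicate 1 (adjusted p = 0.0504, 0.0536 and 0.0504).

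Across the 3 lines, 0 genes were called the same way in every invasion subline, a count that the 0 calls in OECM1 had already fixed. GPX2 was the only gene called the same way in 2 comparisons, lower in the arrays labelled Detroit invasion subline and in Fadu (log2 fold changes of -2.05 and -3.01), and it had 0.66 in OECM1. One such gene compares with 0.0354 expected for independent lists of 159 and 2 lower genes. These lists were not independent, because both comparisons used the same estimate of the spread for each gene. The expected value therefore does not show an excess of sharing, and the GPX2 call in Fadu ended without single Fadu arrays. Across genes, which are not independent replicates, the effects correlated at r = 0.133 between Detroit and Fadu, 0.0363 between Detroit and OECM1 and 0.0424 between Fadu and OECM1. The average over the 3 line pairs had 0 calls in limma, with 387 genes at an unadjusted p under 0.05, and 54 calls when the mean of the 3 contrasts was tested on the 12 arrays.

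The NF-kB and inflammatory cytokine list had a mean below 0 in each line, at -0.83 in the arrays labelled Detroit invasion subline, -0.48 in Fadu and -0.23 in OECM1, beside medians of -0.08, -0.18 and -0.17. Of its 27 members 16, 20 and 18 had negative values in the 3 lines. All 3 values were negative for 7 members and positive for 2, against 7.90 and 0.951 if signs were independent between lines. CXCL1 had log2 fold changes of -5.05, -1.57 and -2.03, CXCL2 of -1.77, -1.17 and -2.04, and CXCL8 of -2.10, -1.20 and -1.48. None of these values in Fadu or OECM1 was called, and other members had positive values, such as IL6 in Fadu and PTGS2 in OECM1. On average over the lines camera called this list lower (mean -0.51, median -0.10, adjusted p = 7.91e-05), with the unfolded protein list higher (0.49, adjusted p = 0.000282). It called matrix proteases (-0.39, adjusted p = 0.00153), NRF2 genes (-0.27, adjusted p = 0.00451), S phase genes (-0.34, adjusted p = 0.00460), cholesterol genes (-0.26, adjusted p = 0.00512), G2 and mitosis genes (-0.36, adjusted p = 0.00633), squamous genes (-0.38, adjusted p = 0.0119) and collagens (-0.25, adjusted p = 0.0368) lower. With an estimated correlation the lowest adjusted p = 0.375, that of the NF-kB list, and the others reached adjusted p = 0.564 to 0.858. For these list tests the average was the mean of the 3 line contrasts fitted to the single arrays. That fit gave 54 calls for single genes, against 0 with the 3 line pairs as replicates. Duplicates served as replicates in it, so the p-values of the list averages leave out the spread between lines. These averages include the arrays labelled Detroit invasion subline. Only the NF-kB list among them had means of the same sign in all 3 lines. Matrix proteases averaged -1.43, -0.08 and 0.34 in Detroit, Fadu and OECM1, S phase genes -0.91, 0.24 and -0.35, and G2 and mitosis genes -1.42, 0.53 and -0.19. Against the Detroit parent mean, subline replicates 1 and 2 gave 0.09 and -2.94 for G2 and mitosis genes. They gave 0.11 and -1.93 for S phase genes and -0.09 and 2.36 for unfolded protein genes.

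**Figure D4:**
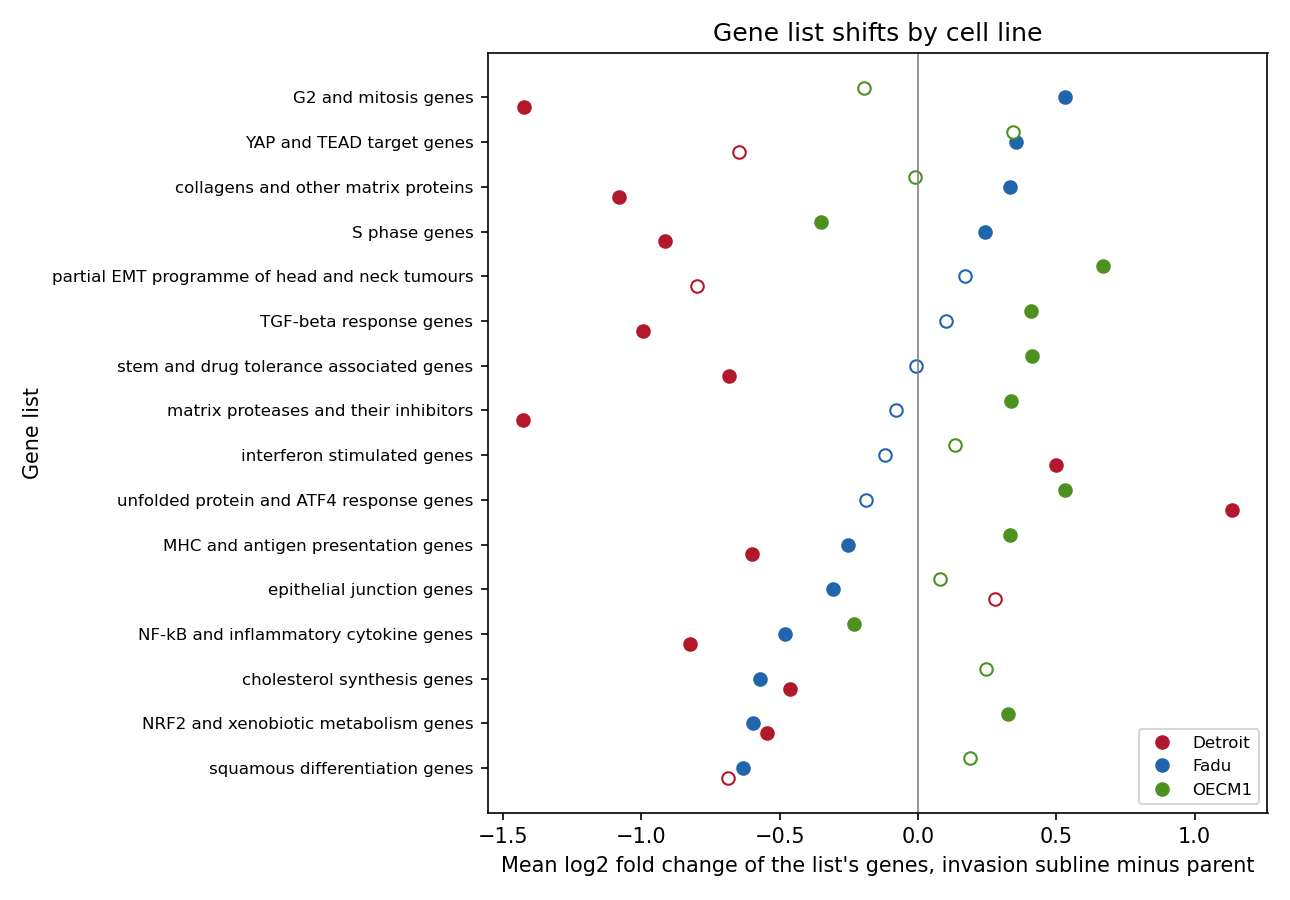
Mean log2 fold change of invasion subline over parent (horizontal axis) for each gene list called in at least 1 line (vertical axis), with 1 point per line, filled where camera with the preset correlation called the list and open where it did not. The NF-kB list has means of -0.83, -0.48 and -0.23 in Detroit, Fadu and OECM1, while the NRF2 list lies at -0.60 in Fadu and 0.32 in OECM1.

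As lists, mesenchymal, integrin, hypoxia and motility genes were not called by camera in any line, though single members were called in the arrays labelled Detroit invasion subline. Of 17 mesenchymal genes 2 fell (2 over the list alone), COL5A2 and the fibronectin gene FN1. Of 18 integrins and laminins 1 fell (3 over the list alone), and of 22 hypoxia genes 2 fell (2 over the list alone). Of 30 actin and motility genes 2 rose and 1 fell (2 and 2 over the list alone). KRT14 was the 1 of 10 basal keratinocyte genes that rose (2 higher and 2 lower over the list alone). Of 19 EGFR family genes 2 fell (4 higher and 3 lower over the list alone), 1 of 10 Notch pathway genes rose (1 over the list alone) and 2 of 26 epithelial junction genes rose (3 over the list alone, camera adjusted p = 0.185). The other members of these lists did not pass, and in Fadu and OECM1 0 members were called. Over the list alone the mesenchymal gene VIM was higher in OECM1, and the hypoxia gene ALDOC, the matrix protease gene MMP13 and, in the stem list, ALDH3A1 were lower in Fadu. Also over the list alone, in the arrays labelled Detroit invasion subline, the simple epithelial gene MUC1 was lower and the endothelial marker EGFL7 higher. ALDOC, MMP13, MUC1 and EGFL7 were named after their values were seen. The mesenchymal list averaged -0.68 in the arrays labelled Detroit invasion subline, 0.23 in Fadu and 0.35 in OECM1 (camera adjusted p = 0.0772, 0.0738 and 0.0738). Integrins and laminins averaged -0.44, 0.13 and 0.27 (adjusted p = 0.0772, 0.194 and 0.0526), hypoxia genes -0.12, -0.17 and 0.31 (adjusted p = 0.491, 0.191 and 0.0653) and actin and motility genes 0.14, 0.18 and 0.19 (adjusted p = 0.644, 0.0886 and 0.195). Basal keratinocyte genes averaged 0.56, -0.01 and -0.05, simple epithelial keratins and mucins -0.53, -0.12 and 0.33, EGFR family genes 0.41, -0.02 and 0.15, and Wnt target genes 0.08, 0.22 and 0.34. Notch pathway genes averaged -0.03, -0.13 and 0.13, p53 target genes 0.17, -0.19 and 0.11, and oxidative phosphorylation genes -0.07, 0.08 and 0.01. Lists of markers of other cell types were not called in any line, with 0 members called. Fibroblast markers averaged -0.57, -0.07 and 0.09, endothelial markers 0.03, -0.08 and -0.09, and leukocyte markers -0.16, 0.04 and 0.00 across 7, 5 and 8 measured genes. Several of these Detroit means average 2 subline arrays of opposite sign against the parent mean, with replicate 1 given first. These were hypoxia genes at -0.63 and 0.40, p53 targets at -0.22 and 0.56, oxidative phosphorylation genes at 0.16 and -0.30 and Wnt targets at -0.08 and 0.23. Notch genes had -0.16 and 0.11, actin and motility genes 0.29 and -0.01, endothelial markers 0.10 and -0.04 and leukocyte markers 0.08 and -0.39.

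With the preset correlation the squamous list was called in Fadu and the partial EMT list in OECM1, and neither was called in Detroit. Both calls ended in camera with an estimated correlation (adjusted p = 0.304 and 0.564). In the arrays labelled Detroit invasion subline, 3 of 28 squamous genes rose, 3 fell and 22 did not pass (5 higher and 6 lower over the list alone, camera adjusted p = 0.0939), and the partial EMT list, of which 2 of 11 genes fell (2 over the list alone), had a mean of -0.80 beside a median of 0.00 (adjusted p = 0.194). In OECM1 the basal keratinocyte list had a mean of -0.05 beside a median of 0.21, and camera gave it a higher direction (adjusted p = 0.791). The interferon list averaged -0.12 in Fadu beside a median of 0.04 (adjusted p = 0.453), with BST2 as its 1 called member. The 1 measured small nucleolar RNA gene, for which no list test was run, had log2 fold changes of 0.52, 0.75 and -1.25 in Detroit, Fadu and OECM1, where it was lower over the list alone.

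The 3 parent lines differed from each other in 476 genes by the F test in limma. S100A8 averaged 11.01 ± 0.553 in the Detroit parent, 4.54 ± 0.242 in the Fadu parent and 3.44 ± 0.0443 in the OECM1 parent (SD, n = 2 each, adjusted p = 1.14e-06). KRT14 was at 8.87 in the Fadu parent against 4.05 in the Detroit parent and 4.42 in the OECM1 parent (adjusted p = 0.00196), and VIM was at 7.29 in the OECM1 parent against 4.86 and 5.02 in Detroit and Fadu (adjusted p = 0.0205). By pairs, 232 genes separated Fadu from Detroit, 264 separated OECM1 from Fadu and 306 separated OECM1 from Detroit. The parent count was 209 without Fadu parent replicate 1, 304 without Fadu parent replicate 2, and 731 and 730 without Detroit invasion subline replicate 1 and 2.

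The difference between invasion subline and parent was itself unequal across the 3 lines in 63 genes by the F test in limma. S100A8 had log2 fold changes of -7.59, -0.87 and 0.00 in Detroit, Fadu and OECM1 (interaction adjusted p = 3.92e-05), KLK5 had 4.80, -1.86 and 0.44 (0.00125), KRT14 had 6.47, -0.02 and -0.47 (0.00467) and GPX2 had -2.05, -3.01 and 0.66 (0.00573). BST2 had -0.35, -2.88 and -0.03 (0.0238), and COL4A1, a basement membrane collagen gene, had -2.34, 1.93 and -0.42 (0.0478). The Detroit values come from the arrays whose mean correlated with the Fadu parent at r = 0.961. The count was 252 without Detroit invasion subline replicate 1, 37 without Detroit parent replicate 1, 38 without Fadu invasion subline replicate 1, 41 without Fadu invasion subline replicate 2, 41 without Fadu parent replicate 1, 41 without OECM1 invasion subline replicate 1 and 38 without OECM1 invasion subline replicate 2. With only the Fadu and OECM1 arrays it was 1. That gene was AKR1C1, an aldo-keto reductase gene, which was 3.42 higher on the log2 scale in OECM1 relative to Fadu (adjusted p = 0.0499).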

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

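The tests of array identity, of the ACTB ratio and of the NRF2 list were chosen only after the results were seen, while the 18S test and the splits of the samples were set before.

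The difference between invasion subline and parent, as labelled, was unequal across the lines in 63 genes by the test of the difference, and 21 named genes were among them. Without the arrays labelled Detroit the count was 1. The range of the log2 fold change over the 3 lines was 6.94 for KRT14, 4.88 for PRSS21, 6.66 for KLK5, 4.98 for SHANK2, 5.03 for EEF1A2 and 4.14 for ARHGAP29. It was 7.59 for S100A8, 5.13 for SLC1A3, 5.09 for MMP7, 5.08 for S100A9, 5.86 for PLAT, 3.67 for GPX2 and 2.85 for BST2. It was 4.45 for MMP10, 4.32 for COL5A2, 4.27 for COL4A1, 3.82 for CXCL6, 3.48 for CD24, 4.66 for AKR1C3, 2.58 for AKR1B10 and 5.77 for KLK10.

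The arrays labelled Detroit invasion subline shared the profile of the arrays labelled Fadu. Over 73 genes private to the Fadu parents, their median positions between the Detroit parents at 0 and the Fadu invasion subline at 1 were 0.824 and 0.926. Cells of a single line under both labels could give such positions. The OECM1 arrays lay between -0.0754 and 0.00452 and the Fadu parent arrays at 1.06 and 0.961. The parent arrays of all lines helped to pick these genes, as genes where the Fadu parent differed from both others. The positions of the Fadu and OECM1 parents therefore followed from that choice, and the OECM1 sublines resemble their parent. They are no independent check. In the arrays labelled Detroit invasion subline 82.2% and 78.1% of the 73 genes lay nearer to the Fadu level, against 98.6% in each Fadu parent array. In the arrays labelled Detroit invasion subline, 28 genes private to the Detroit parents kept a median of 0.593% and 0.409% of their linear signal. The upper quartiles were 2.00% and 1.69%. These values argue against a mixture with at least 10% Detroit cells that kept the parental levels of these genes. Detroit cells that had lowered them would not be seen. Selection that moved a part of the genes of Detroit cells cannot be told apart from one line under both labels, because 88.8% and 90.9% of 232 genes that differ between the parents lay nearer to the Fadu level, short of the bound of 90% in 1 array. No Fadu array lay near the Detroit parents, so no partner of a swap between these groups was seen, and genotyping would be needed.

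Lists whose shift differed between OECM1 and Fadu by camera are given as OECM1 minus Fadu mean log2 fold change. The difference was 0.92 for NRF2 genes (adjusted p = 1.12e-07), 0.82 for cholesterol genes (4.13e-05), -0.73 for G2 and mitosis genes (7.41e-05), 0.82 for squamous genes (8.85e-05), -0.59 for S phase genes (0.000445) and 0.58 for antigen presentation genes (0.00190). It was 0.42 for matrix proteases (0.00929), 0.39 for epithelial junction genes (0.0142), 0.72 for unfolded protein genes (0.0142) and 0.48 for hypoxia genes (0.0146). With an estimated correlation the lowest adjusted p = 0.182.

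The NRF2 list lay lower in the Fadu and higher in the OECM1 invasion subline, a difference of 0.92 (SE over members 0.226), higher in OECM1 for 20 of 25 genes. Without the AKR1C genes, paralogs whose probe sets can share signal, it was 0.71 over 22 genes (adjusted p = 2.73e-05), which argues against those paralogs as the whole cause of the difference. In OECM1 alone the mean without them was 0.22 and camera no longer called the list (adjusted p = 0.0889). A rise in OECM1 apart from these paralogs was therefore not shown. With the ACTB ratio as a covariate the difference was 0.98 (camera adjusted p = 2.75e-07). The ratios were -0.05 and 0.40 in the Fadu subline and 0.55 and -0.23 in its parent. In OECM1 they were 0.06 and 0.63 against 0.87 and 0.04. Subline and parent thus had similar mean ratios in each line. The covariate could move the difference little, so this test decides nothing about RNA quality. A difference between the lines in this programme may remain as a hypothesis, with an adjusted p = 0.182 with an estimated correlation.

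Orienting the 6 duplicate differences by the ACTB ratio, 1 of 4 measures tried without correction, gave a mean correlation across genes of 0.180, and 1 of 32 orientations, that one, reached it, against 0.170 for the highest other. The Detroit parent averaged 0.0144 with the other 5 groups, the rest 0.136 to 0.252, so a direction shared by all 6 was not shown. For the other groups this is consistent with RNA quality or labelling as a source of part of the spread between duplicates. The 18S control gave a mean correlation of -0.0456, reached by 23 of 32 orientations, so no direction shared by the groups followed that control. Only the sign of each difference entered. The test therefore decides nothing about Fadu invasion subline replicate 1, where the 18S control was high. No biological explanation was tested.

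The 18S control probe sets lay above the higher Fadu parent array in Fadu invasion subline replicate 1, by 6.88, 4.53, 6.17 and 4.94 on the log2 scale for 4 probe sets. Among 1812 probe sets with several genes or none listed, outside the genes tested, 61 were called in Detroit and 2 in OECM1.

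For the average over the 3 lines, the 4 splits of the 6 group means were too few for a share under 0.05, with 0 genes in the real split and at most 0 in the others. Over the 12 arrays with the line as a block, the real split gave 0 genes and the highest other gave 1. A count of 0 is reached by every split, so 100 of 100 splits, the real one included, gave as many, and with no calls the count decides nothing about chance.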

How the results depend on the processing

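The crossed replicate block, the ACTB covariate and the fits without the arrays labelled Detroit were chosen only after the results were seen. With array weights the counts were 170 in Detroit and 5 in Fadu. At an adjusted p under 0.01 they were 101 in Detroit, 33 for effects that differ between lines and 189 for the parents, where the stricter threshold is the cause. With only the 4 arrays of a line they were 47 in Detroit and 1 in Fadu. That Fadu gene was SCNN1A (log2 fold change -3.20, adjusted p = 0.0236, limma), and neither GPX2 nor BST2 was called. The ACTB covariate gave 455 in Detroit. Without the arrays labelled Detroit, 1 gene differed between lines. The mean of the 3 contrasts on 12 arrays gave 54 genes on average. At least 2 lines shared 1 gene called the same way, which was 1 for Detroit and Fadu. List calls numbered 40 of 120, 0 with an estimated correlation and 0 with fry. Elsewhere the cause was not tested.

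Arrays with the same replicate number did not deviate together (r across genes -0.186, -0.383 and -0.403), so no pairing by number was shown. The ACTB ratio moved in opposite directions between replicates in the subline and the parent of each line. These correlations therefore cannot exclude a shared day or batch. The replicate number as a block within each line gave 118 genes in Detroit, 0 in Fadu, 29 for effects that differ between lines and 87 for the parents. The crossed replicate block gave 501 genes in Detroit and, with the Fadu and OECM1 arrays alone, 1 in OECM1.

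Leaving out each array in turn gave 128 to 918 genes in Detroit, 0 to 3 in Fadu, 0 to 6 in OECM1, 0 to 0 in all 3 lines, 0 to 0 on average, 37 to 252 for effects that differ between lines, 209 to 731 for the parents and 25 to 52 list calls. Among called lists and genes named in a line it turned the sign of 8 values, uncalled lists left aside. In Detroit these were S phase (-1.93 to 0.11), G2 and mitosis (-2.94 to 0.0870), unfolded protein (-0.0906 to 2.36) and NRF2 genes (-1.16 to 0.0717), in Fadu CCNE2 (-0.013 to 0.83), and in OECM1 S phase genes (-0.79 to 0.0858), MCM6 (-1.70 to 0.039) and PDIA4 (-0.12 to 1.52).

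For 38 called named genes, 522 of 610 alternative results kept direction and threshold, 88 kept direction only and 0 reversed. Each of 31 list results lost its call under some alternative. Array weights and replicate blocks do not apply to the average over group means. Low signals near background compress fold changes.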

Other observations

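Between the arrays labelled Detroit invasion subline and the Fadu invasion subline limma called 1 gene, higher in the former, while 630 genes had an unadjusted p under 0.05 where 449.6 were expected by chance. Group means of these 2 groups correlated at r = 0.948 across genes, which are not independent replicates.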
